A study of Mus musculus with 6 samples.

How the data were processed

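The samples were GFP-positive (replicating) and GFP-negative (quiescent) cells sorted from the livers of 3 CyclinB1-GFP transgenic mice aged 3.5 weeks, with 3 arrays per group. Per the labels' protocols, the liver was perfused, cells were sorted into a phenol reagent, total RNA was purified on columns, and 10 ng per sample was amplified with a whole-transcript kit, converted to double-stranded cDNA and labelled with biotin. The deposited values are 1 intensity per probe set and array, made by the authors with RMA (background correction, normalization between arrays and summary of probes), per the submitters' processing notes. The version and settings of RMA are not given in the sources used here. RMA values usually come as log2, but the deposited intensities are on a linear scale: the lowest was 1.62 and the highest 15836, with array medians between 24.3 and 26.7. Log2 of the deposited intensities was therefore taken first, and no further normalization was made.

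The value table holds 35512 probe sets. In the platform annotation 21789 of them have 1 gene symbol, 1621 have several and 12102 have none, and only those with 1 symbol were named. Symbols were updated through Entrez gene identifiers for 21698 probe sets with a mouse gene table of the GRCm38 assembly, used for names only. Each of 19938 genes was represented by its probe set with the highest mean over the 6 arrays, and 999 genes had more than 1. Of 25 called genes with more than 1 probe set, 0 had another probe set called the other way. No filter on low values was applied. No detection calls were used here, so where a group's mean of a named called gene lay below the array medians, the fold is a lower bound, computed after values under an array's median over all probe sets were raised to it. This floor was chosen after the data were seen and enters no test. Ccnb1 has no probe set of its own among those named here, so its planned difference is not reported, and 89 of the 946 listed symbols were not matched and not analysed here.

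Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 4 residual degrees of freedom and 5.44 prior ones), with the group as the single term and Benjamini-Hochberg adjustment over all 19938 genes at a threshold of 0.05. Fixed before the data were examined were 27 gene lists, 20 of gene function or hepatocyte zone and 7 of markers of other cell types, and they were tested two-sided with camera at a preset correlation of 0.01, adjusted over the 27 lists. Camera with an estimated correlation and fry were run as alternatives, and fry asks only whether a list moves one way on balance. A list member rose or fell if it passed over all genes, and the count adjusted over the list alone stands beside it. Genes were named by a rule fixed at the same time: the 10 largest differences each way among called genes whose groups did not overlap and whose symbols are not clone or predicted names, and for each list the 2 called members with the largest difference on the majority side, or the member with the largest difference where none was called. This gave 48 genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

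The replicate numbers were taken to pair the arrays of 1 mouse. Per the design text, both fractions came from the same 3 livers, but no label says that a number marks a mouse. Xist was high in number 2 of both groups (9.03 in GFP-negative and 9.80 in GFP-positive cells, on the log2 scale) and between 3.73 and 4.04 in the other 4 arrays, while Eif2s3y was low in number 2 of both groups (1.98 and 2.24) and between 6.78 and 7.31 in the others. Deviations from the group means correlated by 0.19, 0.05 and -0.06 across genes for numbers 1, 2 and 3, so the pairing rests on the design text and the sex-linked genes, which do not tell numbers 1 and 3 apart. The fit with the replicate number as a block was run as an alternative with 2 residual degrees of freedom.

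The tests were checked on simulated data for 19938 genes in 3 against 3 arrays, with 50 genes changed at each size. Differences of 0.5, 1, 2 and 3 on the log2 scale were called in 4%, 70%, 98% and 96% of the changed genes, 3.6% of the calls were false, and with the block the shares were 0%, 14%, 90% and 94%. All 5 simulated lists of 40 genes shifted by 0.4 were called and 0 of 5 unshifted ones. Simulated genes were drawn independently, with no correlation within lists and no difference between mice. The simulation therefore does not show how camera's preset correlation or the block behave on genes that move together. Further alternatives were quantile normalization, centring each array on its median, leaving out the genes with the lowest means (13292 stayed), the mean of all probe sets of a gene, an intensity trend, array weights, leaving out each array, all probe sets tested alone, other thresholds, and lists without members shared with another list. Chosen after the data were seen were leaving out both arrays of number 2, leaving the cell division lists out of the background, and the block combined with an estimated correlation.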

Results

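Young CyclinB1-GFP transgenic mice, aged 3.5 weeks and weaned, carry a green fluorescent reporter named after cyclin B1, a protein that accumulates before mitosis. The livers of 3 such mice were dissociated, and fluorescence-activated cell sorting divided the cells into a GFP-positive fraction, which the labels call replicating, and a GFP-negative fraction, which they call quiescent. Total RNA was amplified and hybridised to Affymetrix arrays, giving 3 GFP-positive and 3 GFP-negative arrays labelled as biological replicates. The median intensity per array lay between 24.3 and 26.7, and the number of arrays limits the precision. The comparison asks which transcripts differ between replicating and quiescent cells of the growing liver. Values below are log2 intensities, as mean ± SD over n = 3 arrays per group, and differences are GFP-positive minus GFP-negative ± SE from limma with Benjamini-Hochberg adjustment.

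Genes of mitosis and cytokinesis had the largest measured rises in GFP-positive cells. Prc1 (probe set 10554445), which bundles microtubules of the central spindle, stood at 8.39 ± 0.13 in GFP-positive and 3.69 ± 0.21 in GFP-negative cells, a measured log2 difference of 4.71 ± 0.15 (adjusted p = 1.1e-06). Its GFP-negative level lay below the array medians of 4.60 to 4.74, so its fold is given as a lower bound, at least 13.3-fold. For such bounds values under an array's median were raised to that median. Cdk1 (probe set 10369815), the kinase that drives entry into mitosis, was 22.7-fold higher (9.82 ± 0.13 against 5.31 ± 0.28, adjusted p = 1.2e-06). Top2a (probe set 10390707), a topoisomerase that untangles replicated DNA, was 21.9-fold higher (9.82 ± 0.20 against 5.37 ± 0.08, adjusted p = 1.1e-06). The other 7 of the 10 largest measured rises were those of the condensin subunit Ncapg, the spindle motor Kif11, the kinetochore genes Nuf2, Knl1 and Cenpe, and the spindle-associated genes Hmmr and Ckap2. Nuf2 was 21.9-fold higher, and the other 6, with GFP-negative levels below the array medians, were higher by at least 14.6-fold (Cenpe), 14.9-fold (Ncapg and Ckap2), 15.7-fold (Knl1), 17.6-fold (Hmmr) and 19.5-fold (Kif11). Ccnb1, the gene the reporter is named after, was not analysed here.

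Over 19938 genes, 310 were higher and 23 lower in GFP-positive cells at an adjusted p below 0.05, and 1755 had an unadjusted p below 0.05. The called rises had a median log2 difference of 1.62 and ran from 0.67 to 4.71, with 117 of the 310 below the array medians in GFP-negative cells, while the called falls had a median of -0.95 and ran from -0.68 to -2.24. In each of these 310 and 23 genes the values of one group all lay outside those of the other, as they did in 13.8% of all genes against 10% by chance. Of the 310 higher genes, 121 belonged to the 5 lists of cell division genes described next, and 186 to none of the 27 gene lists. With the replicate number as a block, 327 genes were higher and 28 lower, and these held 296 of the 310 and 12 of the 23.

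**Figure D1:**
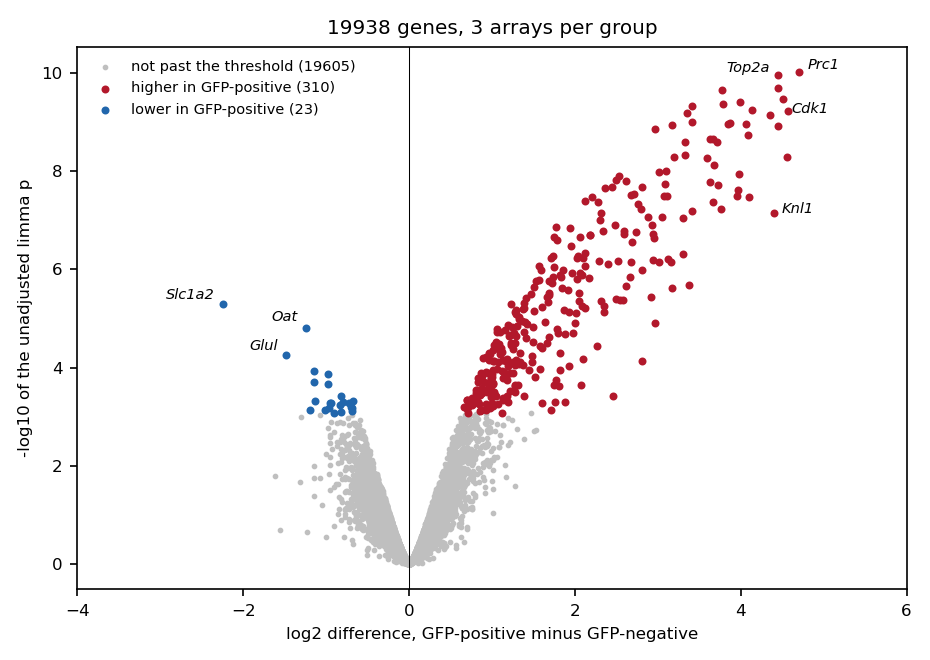
Log2 difference (GFP-positive minus GFP-negative, horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis) for 19938 genes, 1 point per gene, with 3 arrays per group. Red points are the 310 genes higher and blue points the 23 genes lower in GFP-positive cells, and the red points reach a log2 difference of 4.71 (Prc1) while the blue ones reach -2.24 (Slc1a2).

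Of 69 measured genes of G2/M and mitosis, 62 rose and none fell, and 65 rose adjusted over the list alone. The median log2 difference of the list was 2.88 (camera adjusted p = 3.2e-159, or 0.0026 with an estimated correlation between genes), and all 69 members lay above 0. Since the cells were sorted on a reporter named after cyclin B1, a rise of mitosis genes was built into the comparison and mainly checks the sort. Of 23 cytokinesis genes, 13 rose and none fell, with 13 rising adjusted over the list alone (median 1.78, adjusted p = 1.3e-32). Besides Prc1, the cytokinesis list was led by Shcbp1, a midbody protein gene, at 9.11 ± 0.20 against 5.02 ± 0.30 (log2 difference 4.09 ± 0.18, adjusted p = 1.9e-06). Of 49 genes of G1/S and DNA replication, 19 rose and none fell (median 0.71, adjusted p = 3.8e-34), while 32 rose and 1 fell adjusted over the list alone. The genes of both subunits of ribonucleotide reductase, the enzyme that supplies deoxynucleotides, led this list: Rrm2 rose 6.66-fold (log2 difference 2.73 ± 0.20, adjusted p = 5.0e-05) and Rrm1 4.25-fold (2.09 ± 0.19, adjusted p = 0.00025).

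Of 32 genes of the DNA damage response and homologous recombination, 21 rose and none fell, and 24 rose adjusted over the list alone (median 1.16, adjusted p = 8.6e-43). Neil3, a DNA glycosylase gene, was at least 3.28-fold higher (measured log2 difference 2.48 ± 0.18, adjusted p = 3.9e-05), and Brca2, which loads recombinase onto broken DNA, was at least 2.26-fold higher (2.12 ± 0.17, adjusted p = 0.00011). Of 19 replication-dependent histone genes, 6 rose and none fell (median 0.81, adjusted p = 2.3e-14), while 13 rose and 1 fell adjusted over the list alone. H4c6 was at least 4.56-fold higher with a wide spread in GFP-positive cells (6.88 ± 1.14 against 4.42 ± 0.29, adjusted p = 0.027), and H2bc18 was at least 1.36-fold higher (5.09 ± 0.41 against 3.08 ± 0.31, adjusted p = 0.0010). With the same floor the list medians were 2.65 for G2/M, 1.71 for cytokinesis, 0.62 for G1/S, 0.97 for the DNA damage response and 0.67 for the histones. All 5 of these lists also passed with an estimated correlation (adjusted p = 0.0026 to 0.043). With the replicate block and an estimated correlation together, G2/M and mitosis alone passed among all lists (adjusted p = 0.041), and the adjusted p of the other 4 was 0.052 for cytokinesis, 0.052 for the DNA damage response, 0.067 for G1/S and 0.067 for the histones.

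Of 29 cell cycle inhibitors and p53 targets, 2 rose and none fell, with the same counts adjusted over the list alone. Cdkn1a, Bax and Trp53 were among the symbols not matched, so the 29 say nothing about them. The 2 that rose were Rbl1, which encodes the retinoblastoma-related protein p107 and is itself a target of E2F factors (at least 3.04-fold higher, measured log2 difference 2.19 ± 0.16, adjusted p = 5.6e-05), and Cdkn2c, an inhibitor of the cyclin D kinases (4.30-fold higher, 2.10 ± 0.18, adjusted p = 0.00014). The list median was -0.02 while its mean was 0.21, so these differed in sign, and camera placed the list upward (adjusted p = 0.025, or adjusted p = 0.36 with an estimated correlation). Among 31 immediate early and stress genes, Klf6, a zinc finger transcription factor gene, rose 1.95-fold (0.96 ± 0.17, adjusted p = 0.016) and no other member passed. The list as a whole was lower (median -0.18, camera adjusted p = 0.0041, or adjusted p = 0.36 with an estimated correlation), and 1 member rose and 1 fell adjusted over the list alone. None of 35 ribosome biogenesis genes and none of 20 fetal liver and imprinted growth genes passed, over all genes or adjusted over the list alone. The medians of these lists were -0.07 (adjusted p = 0.56) and -0.05 (adjusted p = 0.67). In the first the largest difference was that of Myc (-0.82 ± 0.49, adjusted p = 0.74), and in the second that of Peg3 (0.73 ± 0.20, adjusted p = 0.18).

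The list of genes expressed by hepatocytes around the central vein was lower in GFP-positive cells. Of 28 measured pericentral genes, 4 fell and none rose, 19 fell adjusted over the list alone, and 26 lay below 0. The largest falls were those of Slc1a2, a glutamate transporter gene (5.26 ± 0.13 against 7.50 ± 0.54, 4.73-fold lower, adjusted p = 0.00073), and Glul, the glutamine synthetase gene (8.86 ± 0.46 against 10.34 ± 0.07, 2.79-fold lower, adjusted p = 0.0055). Oat, which encodes ornithine aminotransferase, was 2.37-fold lower (adjusted p = 0.0019), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 1.97-fold lower (adjusted p = 0.017). The list median was -0.61 (camera adjusted p = 1.7e-18, or 0.043 with an estimated correlation), but with the replicate block and an estimated correlation together the adjusted p was 0.15. Between arrays of the same number the mean difference of the list was -0.65, -0.81 and -0.51 for numbers 1, 2 and 3. Of 25 periportal genes, whose hepatocytes lie around the portal vein, none passed over all genes or adjusted over the list alone (median 0.01, adjusted p = 0.73), and the member with the largest difference was Aldh1b1 (0.73 ± 0.33, adjusted p = 0.58). The periportal mean differed by 0.18, -0.41 and 0.41 in numbers 1, 2 and 3. Without both arrays of number 2, a setting chosen after the data were seen, the list median was 0.27 (camera adjusted p = 0.00014 at the preset correlation). The correlation between its members, estimated over all arrays, was 0.40, far above that preset of 0.01.

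**Figure D2:**
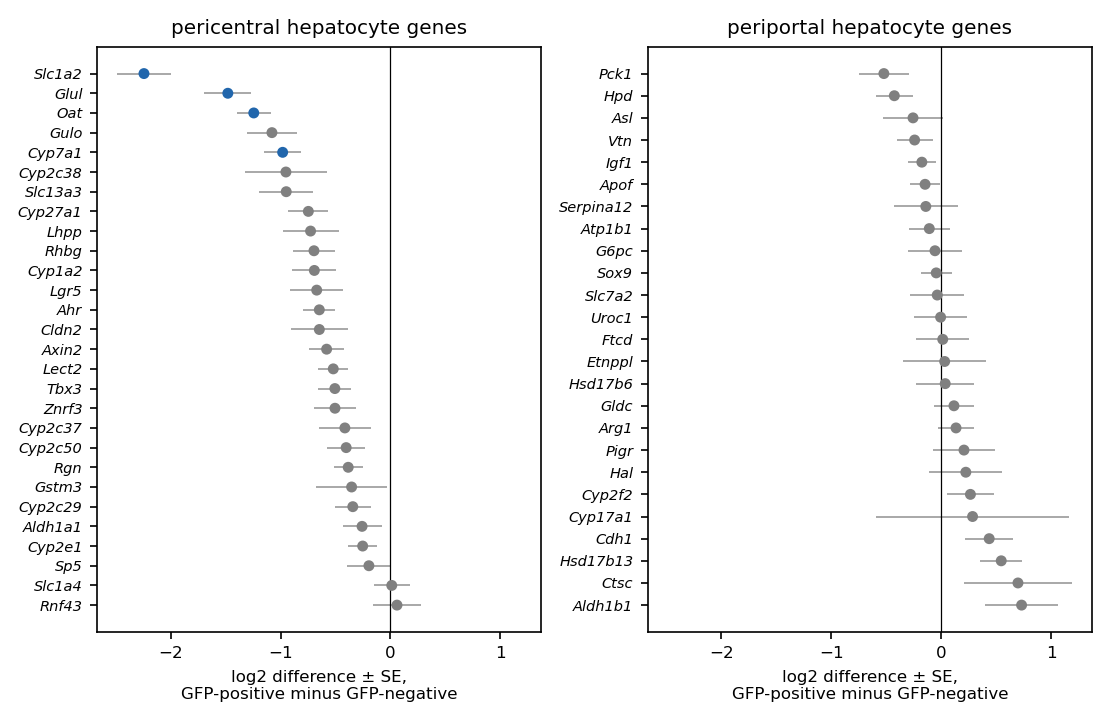
Log2 difference (GFP-positive minus GFP-negative, horizontal axis) of each measured pericentral gene (left, 28 genes) and periportal gene (right, 25 genes), with bars of 1 limma SE and 3 arrays per group. Blue points passed an adjusted p below 0.05 over all genes, and 26 of the 28 pericentral genes lie below 0 against 12 of the 25 periportal genes.

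Bile acid synthesis and transport genes and cytochrome P450 and xenobiotic metabolism genes were lower as lists with camera's preset correlation, but neither list passed with an estimated one. Of 22 bile acid genes, 2 fell and 5 fell adjusted over the list alone (median -0.39, camera adjusted p = 1.7e-07, or adjusted p = 0.14 with an estimated correlation). These 2 were Cyp7a1 and Slco1b2, a hepatic organic anion transporter gene (-0.72 ± 0.14, adjusted p = 0.034, or 0.062 with the replicate block). None of 69 cytochrome P450 and xenobiotic genes passed over all genes or adjusted over the list alone, although 66 lay below 0 (median -0.32, camera adjusted p = 1.6e-11, or adjusted p = 0.077 with an estimated correlation). The member with the largest difference was Cyp4a14, a fatty acid hydroxylase gene (-1.30 ± 0.28, adjusted p = 0.057).

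Lipid metabolism lists were also lower with camera's preset correlation, but none of them passed with an estimated one. Of 37 genes of fatty acid oxidation and ketogenesis, 2 fell, and 2 adjusted over the list alone (median -0.25, camera adjusted p = 8.7e-10, or adjusted p = 0.29 with an estimated correlation). They were Pex11a, a peroxisome division gene (-1.14 ± 0.18, adjusted p = 0.010), and Decr2, a peroxisomal reductase gene (-0.97 ± 0.20, adjusted p = 0.042, or 0.074 with the replicate block). None of 22 fatty acid synthesis genes passed over all genes and 1 fell adjusted over the list alone (median -0.48, camera adjusted p = 6.8e-08, or adjusted p = 0.32 with an estimated correlation). Elovl3, a fatty acid elongase gene, had the largest difference (-1.62 ± 0.55, adjusted p = 0.34, or 0.0062 with the replicate block). None of 20 sterol synthesis genes passed over all genes or adjusted over the list alone (median -0.22, camera adjusted p = 0.0043, or adjusted p = 0.45 with an estimated correlation), and Lss, the lanosterol synthase gene, had the largest difference (-0.61 ± 0.27, adjusted p = 0.57).

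Among 52 genes of the urea cycle and amino acid catabolism, Oat fell and no other member passed, with the same count adjusted over the list alone (median -0.18, camera adjusted p = 7.8e-06, or adjusted p = 0.45 with an estimated correlation). None of 20 genes of gluconeogenesis, glycogen and hexose metabolism passed over all genes or adjusted over the list alone (median -0.29, camera adjusted p = 2.9e-05, or adjusted p = 0.32 with an estimated correlation). Ppp1r3c, a glycogen-targeting phosphatase subunit gene, had the largest difference in that list (-0.80 ± 0.22, adjusted p = 0.18). None of 43 genes of hepatocyte secreted proteins and transcription factors passed over all genes or adjusted over the list alone (median -0.17, camera adjusted p = 0.00036, or adjusted p = 0.32 with an estimated correlation), with the largest difference in Nr0b2 (-0.82 ± 0.35, adjusted p = 0.55). None of 53 oxidative phosphorylation genes passed in either way, and the list did not pass (median -0.07, camera adjusted p = 0.073), with the largest difference in Ndufb10 (-0.37 ± 0.14, adjusted p = 0.44). Replicate number 2 had the largest fall in each of these metabolic and secreted-protein lists. It alone had high Xist and low Eif2s3y, so this cannot be told apart from sex. The mean difference of the urea cycle list was -0.16, -0.62 and 0.13 in numbers 1, 2 and 3, that of the sterol list was -0.12, -0.56 and 0.07, and that of the cytochrome P450 list was -0.37, -0.49 and -0.19. Without both arrays of number 2 the list medians were -0.21 for bile acids, -0.20 for fatty acid synthesis, -0.11 for gluconeogenesis, -0.07 for secreted proteins, -0.05 for sterols and -0.02 for the urea cycle, and the last 4 of these lists did not pass. Without GFP-positive 2 alone the medians were -0.16 for fatty acid synthesis, -0.165 for gluconeogenesis and -0.09 for sterols, of which sterols did not pass.

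**Figure D3:**
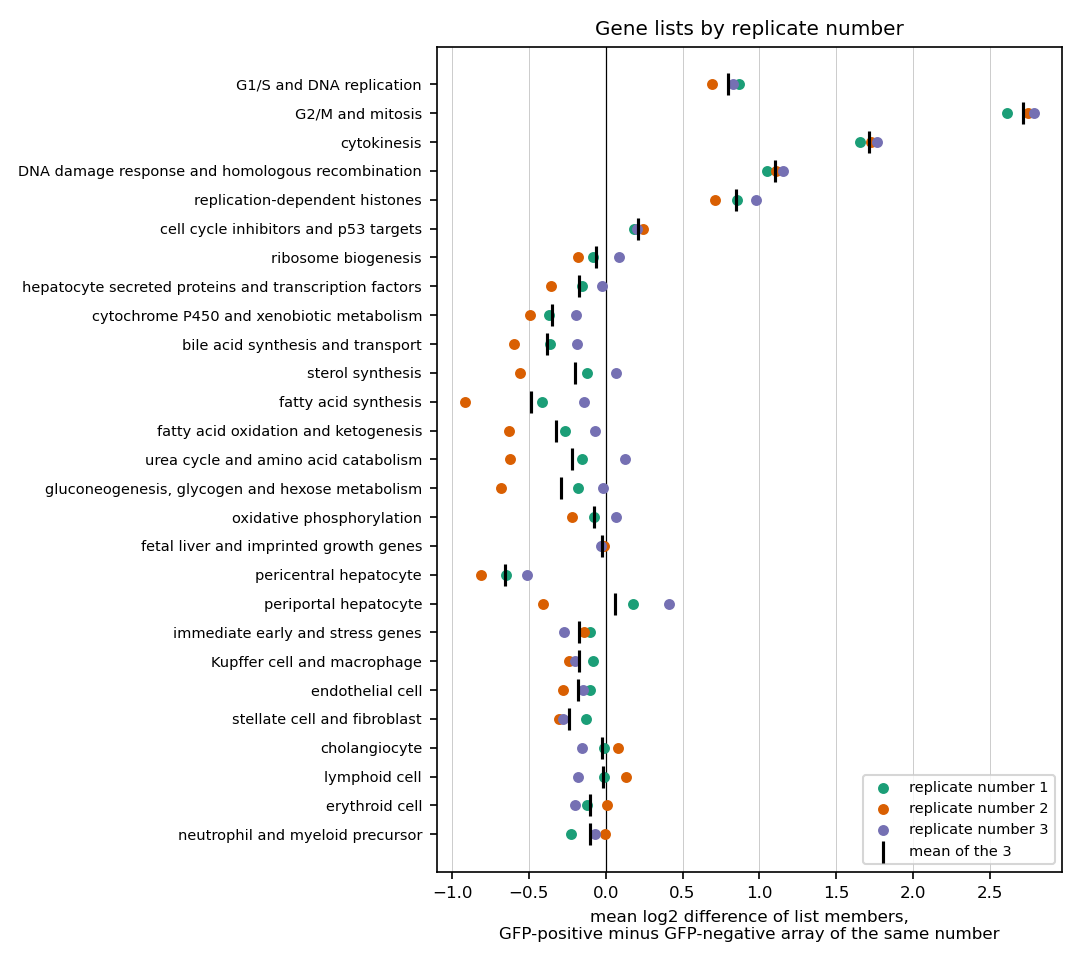
Mean log2 difference of the members of each of 27 gene lists (horizontal axis) between the GFP-positive and the GFP-negative array of the same replicate number, 1 coloured point per number and a black bar for the mean of the 3. The points of the G2/M list lie between 2.61 and 2.78, those of the pericentral list between -0.81 and -0.51, and those of the urea cycle list between -0.62 and 0.13.

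The remaining falls among the 10 largest were those of the cytochrome P450 gene Cyp4a31 (-1.20 ± 0.24), the glycolytic gene Aldoc (-1.14 ± 0.19), the lysosomal membrane gene Mfsd8 (-1.13 ± 0.22), Tmem150a (-1.01 ± 0.21) and the retinol dehydrogenase gene Rdh9 (-0.97 ± 0.16). With the replicate block, 9 of these 10 passed, and Tmem150a had an adjusted p of 0.052.

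Markers of other liver cell types were not raised in GFP-positive cells. Of 24 Kupffer cell and macrophage markers, Clec4f fell (-0.68 ± 0.13, adjusted p = 0.032, or 0.077 with the replicate block) and no other member passed, with the same count adjusted over the list alone (median -0.14, camera adjusted p = 0.029, or adjusted p = 0.29 with an estimated correlation). None of 27 endothelial markers (median -0.17, camera adjusted p = 0.0086, or adjusted p = 0.29 with an estimated correlation) and none of 22 stellate cell and fibroblast markers (median -0.20, camera adjusted p = 0.0015, or adjusted p = 0.14 with an estimated correlation) passed, over all genes or adjusted over the list alone. With the floor at the array medians these 3 list medians were 0.03 (Kupffer), -0.09 (endothelial) and -0.08 (stellate). The Kupffer value is no result about the markers. Of the 24, 18 lay below the floor in GFP-negative cells, and the value equals the offset between the floors of the groups. Cholangiocyte, lymphoid and neutrophil lists gave the same 0.03, and the offset also enters the endothelial and stellate values. Cdh5 differed most among the endothelial markers (-0.71 ± 0.27, adjusted p = 0.44) and Dcn among the stellate markers (-0.86 ± 0.26, adjusted p = 0.24). Lists of 18 cholangiocyte (median -0.02, adjusted p = 0.82), 29 lymphoid (0.00, adjusted p = 0.86), 18 erythroid (-0.07, adjusted p = 0.32) and 21 neutrophil markers (-0.06, adjusted p = 0.64) did not pass, and no member of them did, adjusted over the list alone included. The lymphoid median and mean (-0.02) differed in sign. The largest differences in these lists were -0.31 ± 0.15 for Onecut2, -0.34 ± 0.16 for Igll1, -0.65 ± 0.27 for Car1 and -0.97 ± 0.32 for S100a8, each with an adjusted p of at least 0.33.

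The count of lower genes, 23 with all arrays, changed when single arrays were left out. It was 6 without GFP-negative 1, 11 without GFP-negative 2, 29 without GFP-negative 3 and 9 without any 1 GFP-positive array. Each such fit also has fewer residual degrees of freedom, so lost power and the array left out cannot be told apart. Camera with its preset correlation also called between 8 and 17 lists under the other 9 divisions of the 6 arrays into 3 and 3, none of which gave a list with an estimated correlation.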

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

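The tests of the gene list splits, of cholangiocytes and the 3 blood cell types, of the lists without number 2 and of the pericentral genes were chosen after their results were seen. The gene splits and the test of a general rise in other cell types were set out before. Probe sets outside the named genes also differed when every probe set of the table was tested alone with limma. Among the 12102 probe sets with no gene symbol, 62 were higher and 3 lower in GFP-positive cells, and among the 1621 with several symbols, 14 were higher and 0 lower. These were singled out because the comparison of named genes leaves them out.

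The gene and list counts were set against other divisions of the arrays. Of the 10 divisions of the 6 arrays into 3 and 3, 1, the real one, gave as many as 333 called genes, and the highest of the others gave 0. For lists under camera's preset correlation, 1 of the 10, the real one, gave as many as 19, and the highest other gave 17. With 10 divisions no share below 0.1 can be reached, which is all they can say about chance. The 3 others that also part every pair gave 0 genes each and 16, 12 and 13 lists.

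Lists of hepatocyte metabolism were lower in GFP-positive cells with camera's preset correlation, and none of them passed with an estimated one (adjusted p = 0.077 to 0.45). A general rise in the share of all other cell types among GFP-positive cells would raise the markers of each. The endothelial median was instead -0.1721 ± 0.0469 (SE over 27 markers, none in another list), and -0.0906 ± 0.0407 with values under the array medians raised to them. Its most abundant member Dnase1l3 did not pass by itself (5.90 against 6.58, adjusted p = 0.34). The endothelial list did not pass camera with an estimated correlation (adjusted p = 0.29) and lost its preset call without GFP-negative 2. These values argue only weakly against a general rise and do not address a rise of selected cell types. Stellate markers decide less (-0.1972 ± 0.0517, but -0.0766 ± 0.0533 with that floor). Kupffer markers (-0.138 ± 0.0637) also decide less and cannot be judged with the floor. Their floored median of 0.0301 ± 0.047 is only the offset between the floors of the groups. More cholangiocytes (-0.0212 ± 0.0261), lymphoid (0.0024 ± 0.0247), erythroid (-0.0736 ± 0.0545) or neutrophil cells (-0.0573 ± 0.0652) alone stay open, with medians within 2 SE of 0. A fall in the mouse numbered 2 alone is argued against for cytochrome P450 (median -0.2546 ± 0.0377 without its arrays) and, more weakly, bile acid genes (-0.2082 ± 0.0624). In numbers 1 and 3 the list means differed by -0.37 and -0.19 for cytochrome P450 and by -0.36 and -0.19 for bile acids. Fatty acid synthesis (-0.1974 ± 0.0757) and fatty acid oxidation (-0.1787 ± 0.0357) also lay more than 2 SE below 0. Gluconeogenesis (-0.1083 ± 0.0416) did so too, but it lost its camera call in that setting, where the median over all genes was -0.04. For sterol synthesis (-0.0469 ± 0.0335) and the urea cycle (-0.0233 ± 0.0419) the fall outside that mouse was within 2 SE of 0, as such an origin predicts. Each SE is the SD over genes divided by the square root of their number, so it is an SE of the mean set beside a median. It treats genes as independent and holds no spread between mice. The estimated correlation was 0.07 for cytochrome P450, 0.15 for bile acids, 0.35 for fatty acid oxidation, 0.37 for gluconeogenesis and 0.58 for fatty acid synthesis. These SE are therefore too small, and outside cytochrome P450 a median beyond 2 SE decides little. Number 2 was the 1 mouse with high Xist and low Eif2s3y, the pattern of a female. What sets it apart cannot be told from sex, which was not tested.

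The pericentral list was lower in all 3 numbers. A fall of all hepatocyte transcripts together would move it as much as the secreted-protein list, if the arrays respond alike at both levels. The pericentral mean lay lower by more than 2 SE (difference -0.4798 ± 0.0934 over genes, means -0.66 and -0.18). The lists differ in level (8.53 and 10.80 in GFP-negative cells), and an equal response was not tested. This SE also treats genes as independent, with estimated correlations of 0.14 and 0.15. A candidate explanation is that replicating hepatocytes lay nearer the portal vein; the periportal mean, which it predicts above 0, was 0.0622 ± 0.0627, so this cannot be told apart from a fall of pericentral transcripts during division. Pericentral minus periportal was -0.83, -0.40 and -0.93 in numbers 1, 2 and 3, below 0 in 3 of 3, which either explanation predicts. What keeps the question open is the spread of the periportal list between mice. Its mean differed by 0.18, -0.41 and 0.41, so it went the other way in number 2.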

How the results depend on the processing

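Leaving out both arrays of number 2, the replicate block combined with an estimated correlation, and a background without the cell division lists were chosen after the data were seen. The count of higher genes stayed within 1.5 times of 310 in every setting run (228 at an adjusted p below 0.01 to 405 with array weights, and 244 to 294 without each array in turn). The count of lower genes, 23, was 28 with the replicate block, 38 with quantile normalization, 13 with median centring, 53 with array weights, 9 without number 2, 6 among all probe sets tested alone, 8 at 2-fold or more and 3 at an adjusted p below 0.01, and it ran from 6 (without GFP-negative 1) to 29 (without GFP-negative 3). Of the 19 called lists, 6 (the 5 of cell division and the pericentral list) kept their call and direction in every alternative except the block with an estimated correlation. At camera's preset correlation the block changed no list call, and its other changes were the counts and named genes given with it in the report and 1 gene each of the Mcm and nucleoporin families. With an estimated correlation, and with the block added to it, calls were lost at unchanged medians for cell cycle inhibitors (-0.0248), secreted proteins (-0.173), cytochrome P450 (-0.3184), bile acids (-0.3886), sterols (-0.2228), fatty acid synthesis (-0.475) and oxidation (-0.2513), the urea cycle (-0.181), gluconeogenesis (-0.2916), immediate early genes (-0.1805), Kupffer (-0.138), endothelial (-0.1721) and stellate cells (-0.1972). Fry lost the same ones except cytochrome P450, bile acids and stellate cells. The block with an estimated correlation also lost G1/S (0.7067), cytokinesis (1.7804), DNA damage (1.1627), histones (0.807) and the pericentral list (-0.614); the block leaves fewer degrees of freedom to estimate the correlation from. Quantile normalization ended the calls of secreted proteins (-0.1258) and Kupffer cells (-0.1851), the filter on low values that of Kupffer cells (-0.1948), and array weights that of the inhibitors (0.0079). Oxidative phosphorylation passed with a trend (-0.0713) and with array weights (-0.0784). Without number 2, calls were lost for the inhibitors (-0.0282), secreted proteins (-0.071), sterols (-0.0469), gluconeogenesis (-0.1083), Kupffer (-0.1834) and endothelial cells (-0.1017). Camera's direction then turned for ribosome biogenesis (0.0194), the urea cycle (-0.0233) and oxidative phosphorylation (-0.025). The bile acid (-0.2082) and fatty acid synthesis (-0.1974) medians shrank but passed, and the periportal list passed upward (0.2694, adjusted p = 0.00014, against 0.00064 to 0.95 without single arrays); the cause was not tested. Leaving out single arrays moved the inhibitors from -0.0435 (without GFP-positive 2) to 0.0846 (without GFP-negative 3), and their call was lost without either of these or GFP-negative 1. Sterols ran from -0.2648 to -0.0948 and were lost without either array of number 2. The urea cycle (-0.2784 to -0.1017), immediate early genes (-0.2445 to -0.1412) and endothelial cells (-0.2024 to -0.1104) were all lost without GFP-negative 2. Kupffer cells ran from -0.1845 to -0.0919 and were lost without GFP-negative 2, GFP-positive 1 or GFP-positive 3. Fatty acid synthesis (-0.6 to -0.1608) and gluconeogenesis (-0.3521 to -0.165) kept their calls but had their smallest falls without GFP-positive 2, and gluconeogenesis was at -0.1892 without GFP-negative 2. Fatty acid oxidation was at -0.3788 and the urea cycle at -0.2784 without GFP-negative 3, and endothelial cells at -0.1104 without GFP-positive 1. Oxidative phosphorylation (-0.1424 to -0.0305) passed without GFP-negative 3, and the periportal list (-0.0996 to 0.1945) passed without GFP-negative 2 and turned without GFP-negative 1, GFP-negative 3 or GFP-positive 3. Lists that never passed changed camera's direction with ranges of -0.1524 to 0.0647 for ribosome biogenesis, -0.1276 to 0.0056 for fetal genes, -0.0382 to 0.0432 for cholangiocytes, -0.0369 to 0.0794 for lymphoid cells and -0.0857 to 0.0203 for neutrophils. Among 33 called named genes, 392 of 461 alternative values kept the call, 69 lost it and 0 turned; median centring lost H4c6, Cyp4a31, Mfsd8, Tmem150a and Decr2. Low signal limits the marker lists among others, since array medians lay between 4.60 and 4.74 on the log2 scale and, for example, 18 of 24 Kupffer and 20 of 29 lymphoid markers lay below them in GFP-negative cells. Ccnb1 was not analysed here under any setting.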

Other observations

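The gene families here were picked by symbol after the called genes had been seen, and the Fisher tests (one-sided, exact, over 19938 genes, Benjamini-Hochberg over 10 families) describe them. Centromere genes were the family with the largest share of raised members: 14 of 21 Cenp genes rose (median log2 difference 1.68, adjusted p = 3.8e-20), of which 3 are in the fixed lists, and the others include Cenph, Cenpi, Cenpk, Cenpn, Cenpu and Cenpw of the inner kinetochore. All 14 also rose with quantile normalization, median centring and the replicate block, and 11 without number 2. Of 40 kinesin genes, 11 rose (median 0.10, adjusted p = 8.3e-11), all of them in the fixed lists and all 11 also past the threshold under each of those 4 settings. Of 37 centrosomal Cep genes, 9 rose (median 0.28, adjusted p = 1.3e-08), among them Cep55, Cep192 and Cep290, and 7 of the 9 passed with quantile normalization, 8 with median centring, 9 with the replicate block and 6 without number 2.

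In the other 7 families 2 or 3 members rose. Haus1, Haus6 and Haus8, 3 of 7 genes of the augmin complex, which nucleates microtubules within the spindle, rose (adjusted p = 0.00031), as did the Fanconi anaemia genes Fancb, Fancd2 and Fanci (3 of 10, adjusted p = 0.00069) and the helicase genes Mcm5, Mcm7 and Mcm8 (3 of 10, adjusted p = 0.00069). The Lsm genes of RNA processing had a median of -0.02 although Lsm2, Lsm3 and Lsm5 rose (3 of 13, adjusted p = 0.0014). Among the tubulins, Tubb5, Tubb6 and Tubd1 rose (3 of 16, adjusted p = 0.0022), among importins and exportins Cse1l, Kpna2 and Xpo1 (3 of 21, adjusted p = 0.0045), and among nucleoporins Nup107 and Nup160 (2 of 20, adjusted p = 0.038). Of the 3 Mcm genes, 2 passed with median centring, 2 with the replicate block and 2 without number 2, and of the 2 nucleoporin genes, 1 passed with median centring and 1 with the replicate block. Without number 2, 2 of the 3 augmin, tubulin and Lsm genes each and 1 of the 3 importin and exportin genes passed, while all 3 Fanconi genes passed in each of the 4 settings. No member of the 10 families fell.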
